A study of Homo sapiens with 2 samples.

How the data were processed

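DNA of 1 HEK293T library made by NTD-seq and 1 made by BS-seq was compared, and the group of each was taken from its label. Per the labels' protocols, unmodified lambda phage DNA and a methylated spike-in were added before oxidation by nTET and deamination, the DNA was sheared to 200 to 400 bp, and the NTD-seq product went through 2 rounds of PCR. The text given here for the BS-seq protocol was incomplete, so its steps are not described. The submitters' processing notes name FastQC 0.11.8, cutadapt 3.5, Trimmomatic 0.39, Bismark 0.24.0, SAMtools 1.9 and the build GRCh38.p13, without the role of each. Whether duplicate reads were removed is not given in the sources used here.

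The deposited tables have 1 line per called cytosine, with its position, strand, context, and the count of methylated and of unmethylated reads as the authors made them. The methylation level deposited beside them is a fraction, and it equalled methylated reads over all reads on every line (0 lines differed by more than 1e-06). The last columns hold a p-value and a q-value deposited by the authors. Tested on the tables, the smallest depth was 5 reads, the smallest level 5% and the largest q 0.00978 in NTD-seq and 0.00977 in BS-seq. The p-values of the authors behaved as the one-sided binomial tail of the counts against a constant rate, which was recovered from up to 200 pairs of counts per library and context. That rate was 0.177% for CpG, 0.969% for CHG and 0.155% for CHH in NTD-seq, and 0.300%, 0.306% and 0.305% in BS-seq. The rates set how few methylated reads make a call, so numbers of calls depend on them. At a depth of 10 reads the fewest methylated reads of a CHH call were 2 in NTD-seq and 3 in BS-seq. No spike-in or mitochondrial sequence was analysed here. Calls on other sequences than chromosomes 1 to 22 and X were left out, 48,958 in NTD-seq and 45,082 in BS-seq.

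Because cytosines with no call are absent, the files cannot give coverage or the level of unmethylated DNA, and levels were taken over called cytosines. The overlap of calls took the place of sites covered, as fixed before the data were examined. Comparisons of sites, bins and genes used CpG cytosines called in both libraries. The total depth of these was 330,473,234 reads in NTD-seq and 271,575,525 in BS-seq. Levels were pooled over reads (methylated over all reads), with 95% Wilson intervals, and differences with Newcombe intervals built from them. These cover counting error only. Correlations are across sites or bins, with Fisher's z intervals. Variance beyond counting was the variance of the difference over the binomial variance of both values. Fisher's exact test (two-sided) was run per CpG cytosine with at least 10 reads in both, adjusted by Benjamini-Hochberg, and sites were counted at an adjusted p under 0.05 and at least 20 points. The test was tested on simulated data of 200000 sites, where it called 0.164% of sites changed by 30 points, 4.16% of those changed by 50 points and 0.000509% of unchanged ones. The adjustment there ran over the simulated sites alone, and unchanged sites had no offset between the libraries. These shares are therefore not the exact rates of the real test.

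No genome sequence and no strand of genes was used here. Analyses that need them, of CpG islands, coverage by GC content, the base next to each CpG read from the genome, and windows around gene starts, were planned and not run. For promoters the gene region was used in their place: the span of the gene with 1000 bp on each side, with at least 5 CpG cytosines called in both and 50 reads in each library. Gene bodies were spans of at least 5000 bp trimmed by 2000 bp at both ends, with at least 20 cytosines and 200 reads. Gene ends were pooled without regard to which is the start. The base before the C was inferred only where another CpG was called 2 bp upstream. Genes came from the RefSeq table of assembly GRCh38.p14, whose chromosomes have the same sequence as those of GRCh38.p13. The table was used only to assign calls to genes, and the positions printed are those of the first and last called CpG in the authors' files. Of 19,974 protein-coding genes 19,469 were measured. Gene regions were also tested on simulated data at the real depths of these 19,469 regions, where 97.5% of those lowered by 15 points, 100% of those lowered by 30 points and 0.0367% of unchanged ones were counted as differing. The unchanged regions were simulated with no offset between the libraries. Their share therefore does not tell how often a region with the common offset of the real data passes by counting error.

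A gene was counted as differing when the levels were at least 10 points apart and the Wilson intervals did not overlap. The rule for named genes was fixed before the data were examined, for promoters, and was then applied to the gene regions that took their place: the 10 gene regions and the 5 gene bodies with the largest difference in each direction among those with separate intervals, and in each gene group the members with the highest, the median and the lowest NTD-seq level. In the positive direction only UCN3 met it. Other named genes are marked in the text, and 1 gene that the rule takes is not reported here. The 13 gene groups were also fixed before the data were examined; they were housekeeping, imprinted, germline, developmental regulator, HOX, protocadherin, olfactory receptor, cancer, DNA methylation machinery, kidney epithelium, neuron, blood cell and other tissue genes. Each group's median difference was placed among 10000 random groups of the same size, matched in 10 classes of mean level. C1orf43 was found under the symbol LTAP1. H19, SOX1 and SOX2 had too few calls.

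Alternatives changed the minimum of reads, the weighting, the deepest sites (above 58 reads in NTD-seq or 38 in BS-seq), the difference required, the depth by thinning, the bin size, the gene window, and the background rate. Those for promoter windows, islands and flanking bases could not be run. Values were computed with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and numba 0.67.0, and plots were drawn with matplotlib 3.10.9.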

Results

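Genomic DNA of HEK293T, an established line of human embryonic kidney cells, was mapped for 5-methylcytosine at single-base resolution with NTD-seq and with whole-genome bisulfite sequencing (BS-seq). In NTD-seq a TET enzyme first oxidises the modified cytosines and a deaminase then converts the cytosines that are left, so no bisulfite is used. In both assays a methylated cytosine is read as C and an unmethylated one as T. There was 1 library per method and no replicate, so every difference below compares these 2 libraries and carries counting error alone. The deposited tables list cytosines called as methylated, each with its methylated and unmethylated reads. Cytosines with no call are absent from them, so every level below is a mean over called cytosines and lies above the level of all cytosines in the same stretch. The NTD-seq table held 35,295,815 calls and the BS-seq table held 33,964,562. At CpG calls on chromosomes 1 to 22 and X the total was 396,057,271 reads in NTD-seq and 320,297,514 in BS-seq, with a mean depth of 11.5 and 9.52 reads.

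The first comparison asked whether both methods find the same methylated CpG cytosines. CpG sites made up 97.6% of the NTD-seq calls and 99.2% of the BS-seq calls. Of 40,394,212 CpG cytosines called in either library, 27,631,352 (68.4%) were called in both, 6,753,857 in NTD-seq alone and 6,009,003 in BS-seq alone. The overlap rose with depth. Among NTD-seq calls with 5 to 9 reads 74.2% were also called by BS-seq, and among those with 40 reads or more 90.2% were. Calls at low levels were shared less often, with 48.1% of the NTD-seq calls under a level of 20% and 82.8% of those at 80% or more found in BS-seq.

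CpG methylation was lower in the NTD-seq library on every chromosome. Over all called CpG cytosines the level was 71.8% (95% Wilson interval 71.806 to 71.815) in NTD-seq and 78.3% (78.288 to 78.297) in BS-seq. At the CpG cytosines called in both, it was 73.8% and 79.7%, a difference of −5.84 percentage points (95% interval −5.85 to −5.83). All 22 autosomes and chromosome X had the lower value in NTD-seq, from −5.40 points on chromosome 13 to −7.69 on chromosome 16. Chromosome 17 had the highest autosomal level in both libraries, 78.6% in NTD-seq and 84.6% in BS-seq. Chromosome 16 had the lowest autosomal level, 65.8% and 73.5%, and chromosome X lay below every autosome, at 63.2% and 68.9%. The place of chromosome 16 held only for pooled reads. As medians over bins of 100 kb it had 74.7% in NTD-seq and 80.5% in BS-seq, with a difference of −5.82 points. By that measure chromosome 21 was the lowest autosome, at 64.9% and 69.4%, and chromosome 19 had the largest difference, −6.06 points. The intervals cover counting error only, since reads of a PCR-amplified library without molecular identifiers are not independent molecules.

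The size of the difference followed the level of the site. CpG dyads were sorted by the BS-seq level of one strand, and both libraries were then read on the other strand. In the class where the sorting strand was at 95 to 100%, the level was 87.7% in NTD-seq and 93.4% in BS-seq (−5.66 points, interval −5.68 to −5.64, 1,001,661 cytosines). In the class of 5 to 20% it was 17.1% and 19.9% (−2.81 points, interval −2.87 to −2.75, 93,360 cytosines). In the top class, after thinning to 10 reads per cytosine, every read was methylated at 32.2% of cytosines in NTD-seq and at 53.8% in BS-seq. CpG cytosines next to another called CpG had higher levels, and the difference was larger there. With a G before the C it was −6.31 points (79.2% and 85.5%, interval −6.38 to −6.25), with a C after the G −6.49 points (78.7% and 85.2%, interval −6.55 to −6.42), and with no CpG call next to it −5.63 points (69.6% and 75.3%, interval −5.64 to −5.62). A neighbour was seen only if called as methylated, which selects for higher levels, and the difference grew with the level. The class without such a call also takes in CpG neighbours that were not called. These classes therefore cannot show an effect of the flanking base itself. Within dyads the mean level did not differ detectably with a G before the C. In 46,465 dyads with a G before the C on one strand alone, that strand exceeded its partner by 0.0494 points (interval −0.0784 to 0.177) in NTD-seq and by −0.0568 points (interval −0.177 to 0.0635) in BS-seq.

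**Figure D1:**
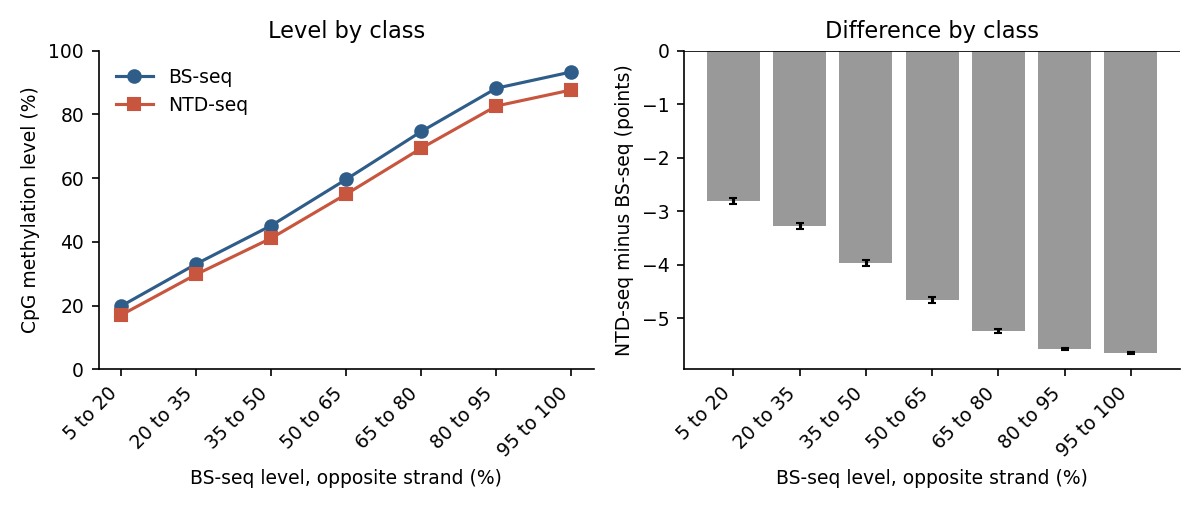
CpG methylation level in percent (left) and the difference NTD-seq minus BS-seq in percentage points with 95% intervals for counting error (right), for CpG cytosines sorted by the BS-seq level of the opposite strand. NTD-seq lies below BS-seq in each class, by −2.81 points in the lowest class and −5.66 points in the highest.

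Single CpG cytosines agreed less closely than regions did. Over the 8,258,640 CpG cytosines with at least 10 reads in both libraries, Pearson's r across sites was 0.803 (interval 0.803 to 0.803) and Spearman's rho was 0.691. The difference NTD-seq minus BS-seq had a mean of −5.06 points and an SD of 15.05 points. Its variance was 1.11 times what binomial counting gives. For the 2 strands of a CpG inside the BS-seq library that ratio was 0.977, and inside the NTD-seq library it was 1.25, so the strands of NTD-seq differed from each other by more than counting error and those of BS-seq did not. Sites are not independent replicates, and no p is attached to these values.

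Fisher's exact test (two-sided, Benjamini-Hochberg adjusted over all tested sites) called 20 CpG cytosines lower in NTD-seq by at least 20 points and 0 higher. Of the 8,258,640 tested, 251,566 had an unadjusted p under 0.05. That is a smaller share than the limit of 0.05 allows without any difference, so the count alone is no sign of an excess. Of the 20 called sites, 12 lay within chromosome 21 from 8219670 to 8219714 (GRCh38.p13), outside any gene of the annotation used here. The NTD-seq level there was 8.25 to 15.9% and the BS-seq level 41.2 to 47.1%. Depth in this cluster was 82 to 165 reads in NTD-seq and 102 to 153 in BS-seq, against means of 11.5 and 9.52 over all CpG calls. The only called site inside an annotated gene was in AK5, an adenylate kinase, at position 77466710 of chromosome 1, with 34.4% of 32 reads in NTD-seq and 100% of 21 reads in BS-seq; like the cluster on chromosome 21, it was singled out after its values were seen. The test compares the libraries, not the methods. In simulated data at these depths it called 0.164% of sites changed by 30 points and 4.16% of those changed by 50 points, which points to little power. Those shares were adjusted over 200000 sites and not over all tested ones, so they are a rough guide. Without the deepest sites the test called 0.

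The libraries gave nearly the same regional map of the genome. Over 28,627 bins of 100 kb, Pearson's r was 0.996 and Spearman's rho 0.995. NTD-seq was the lower in 28,559 bins and the higher in 68, with a median difference of −5.61 points. Bin levels had 2 peaks. A peak here is a class of 5 points that is fuller than the classes beside it. In BS-seq the peaks were at 85 to 90% (6990 bins) and 50 to 55% (2060 bins). In NTD-seq they were at 75 to 80% (6681 bins) and 45 to 50% (2143 bins), with nearly as many bins at 80 to 85% (6503) as at the main peak. Bins under 65% in BS-seq made up 24.6% of all bins. That limit is a line through a range, with 2907 bins within 5 points of it. The bins of lower level held few called CpG cytosines, with a median of 348 per bin between 50 and 65% against 1216 per bin at 80% or more. They made up 59.8% of chromosome X, 46.3% of chromosome 21 and 41.0% of chromosome 8, against 11.2% of chromosome 13.

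**Figure D2:**
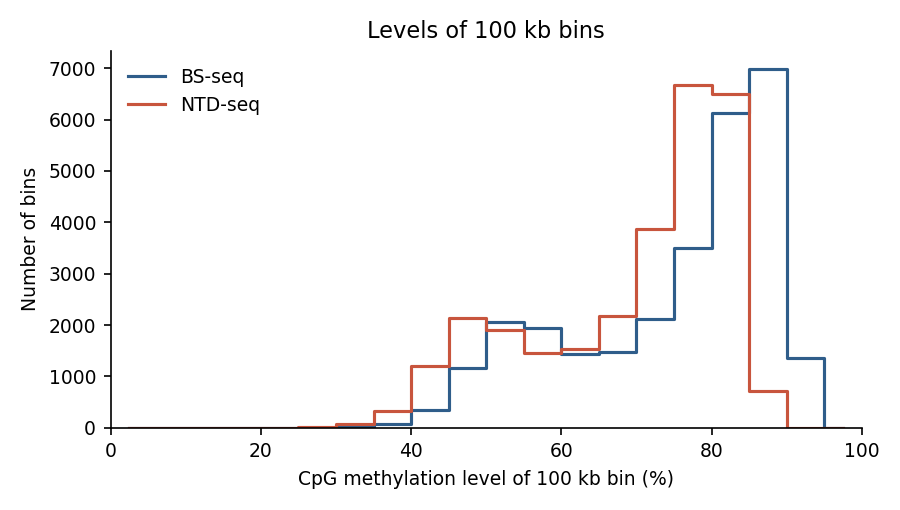
Number of 100 kb bins (vertical axis) by CpG methylation level in percent (horizontal axis, classes of 5 points) in BS-seq and NTD-seq. Each library has a main peak and a smaller one, at 85 to 90% and 50 to 55% in BS-seq and at 75 to 80% and 45 to 50% in NTD-seq.

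The bin with the largest fall in NTD-seq lay on chromosome 22. In the bin from 50800001 to 50900000 on chromosome 22 the level was 56.3% in NTD-seq and 82.9% in BS-seq (−26.5 points, interval −29.8 to −23.1, 86 cytosines), at a mean depth of 21.4 and 10.2 reads. In the bin from 600001 to 700000 on chromosome 1, which holds the olfactory receptor gene OR4F16, it was 44.3% and 61.2% (−17.0 points, interval −19.3 to −14.7), at a mean depth of 20.3 and 9.52 reads. In both bins the depth of NTD-seq exceeded that of BS-seq by more than it did over all CpG calls. In the other direction the largest difference was 6.34 points (interval 1.34 to 11.3), with 62.9% in NTD-seq and 56.6% in BS-seq over the 51 cytosines of the bin from 61300001 to 61400000 on chromosome X. These bins were singled out after their values were seen.

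Protein-coding genes carried the same offset almost without exception. Of 19,469 gene regions measured (the gene with 1000 bp on each side), 98.6% had the lower level in NTD-seq, with a median difference of −5.78 points. The median level was 80.5% in NTD-seq and 86.4% in BS-seq. Regions at 80% or more numbered 10,403 in NTD-seq and 14,905 in BS-seq, while 3 and 0 were under 20%. With Wilson intervals that did not overlap, 415 regions were lower in NTD-seq by at least 10 points and 0 were higher by as much. The common offset counts toward these 10 points, so the 415 are not a count of departures from that offset. Averaging over sites in place of reads gave 233, and a difference of at least 20 points left 11. Gene bodies gave the same picture. Among 15,945 gene bodies the median was 82.0% in NTD-seq and 87.8% in BS-seq, 213 were lower in NTD-seq by at least 10 points with separate intervals and 0 were higher by as much.

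Of the 10 gene regions with the largest falls in NTD-seq, 3 were olfactory receptor genes, which encode odorant receptors. Reads of gene families with similar copies cannot always be told apart, and most of these regions held few cytosines. OR2T33 (chromosome 1, called CpG from 248273429 to 248275635) had 48.7% of 78 reads in NTD-seq and 76.1% of 71 reads in BS-seq, a difference of −27.3 points (interval −41.0 to −11.8). OR4F5 (chromosome 1, 64564 to 70666) differed by −24.9 points (interval −37.7 to −10.7) and OR5M10 (chromosome 11, 56576114 to 56578387) by −21.0 points (interval −32.3 to −8.91). POU5F1B, a retrotransposed copy of the pluripotency gene POU5F1 (chromosome 8, 127413544 to 127417996), had 37.3% and 59.2% (−22.0 points, interval −29.8 to −13.7). DEFB106A, a beta-defensin gene, and FOXD4L1, a forkhead gene, differed by −21.4 and −21.3 points, on 10 and 9 cytosines. ACTL9, an actin-like gene, differed by −20.7 points (interval −28.8 to −12.0), FAM43B by −24.6 points (interval −32.4 to −16.4) and LOC105375816 by −21.9 points (interval −36.3 to −6.57).

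Among the gene regions with the largest differences, a pair changed beyond counting error with how sites were weighted. PGRMC1, which encodes a heme-binding membrane protein (chromosome X, 119235295 to 119245441), had 41.4% of 2839 reads in NTD-seq and 62.9% of 1334 reads in BS-seq, or −21.5 points (interval −24.6 to −18.3). Its difference was −10.0 points without the deepest sites and −5.38 points as a mean over sites. UCN3, the gene of the peptide hormone urocortin 3 (chromosome 10, 5363974 to 5375683), was the only gene region with separate intervals and the higher level in NTD-seq, 67.0% against 62.3% (4.65 points, interval 1.53 to 7.81). Without the deepest sites it was 4.85 points, and averaged over sites it reversed to −5.63 points. Its gene body did the same, with 6.63 points weighted by reads and −6.27 points as a mean over sites.

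Among gene bodies the largest fall was in BMP4. BMP4, a growth factor of the TGF-beta family (chromosome 14, 53954034 to 53954813), had 41.0% in NTD-seq and 60.9% in BS-seq (−19.8 points, interval −26.2 to −13.2). VGLL2, a transcriptional cofactor (chromosome 6, 117267707 to 117271574), had 56.3% and 75.8% (−19.5 points, interval −22.7 to −16.2). As a mean over sites the difference of VGLL2 was −14.2 points. ANKRD34A differed by −17.7 points (interval −25.5 to −9.62) and EXOC3L1 by −17.1 points (interval −23.0 to −10.8). LOC102724250, in the same part of chromosome 1 as the bin named above, differed by −18.0 points weighted by reads and by −11.4 points as a mean over sites.

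Called CpG cytosines thinned out at the ends of genes in both libraries. Over 14,316 protein-coding genes longer than 10000 bp, the first 100 bp inside a gene end held 1.12 calls per end in NTD-seq and 1.06 in BS-seq, against 1.81 and 1.75 per 100 bp between 4000 and 5000 bp inside. At the sites called in both, the level in that first step was 74.2% in NTD-seq and 80.7% in BS-seq. Between 4000 and 5000 bp inside it was 80.4% and 86.3%. The difference was −6.48 points at the end and −5.95 points inside. The lowest step of NTD-seq was this first one inside, while that of BS-seq lay outside the gene, 500 to 600 bp from its end, with 74.4% in NTD-seq and 80.6% in BS-seq.

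**Figure D3:**
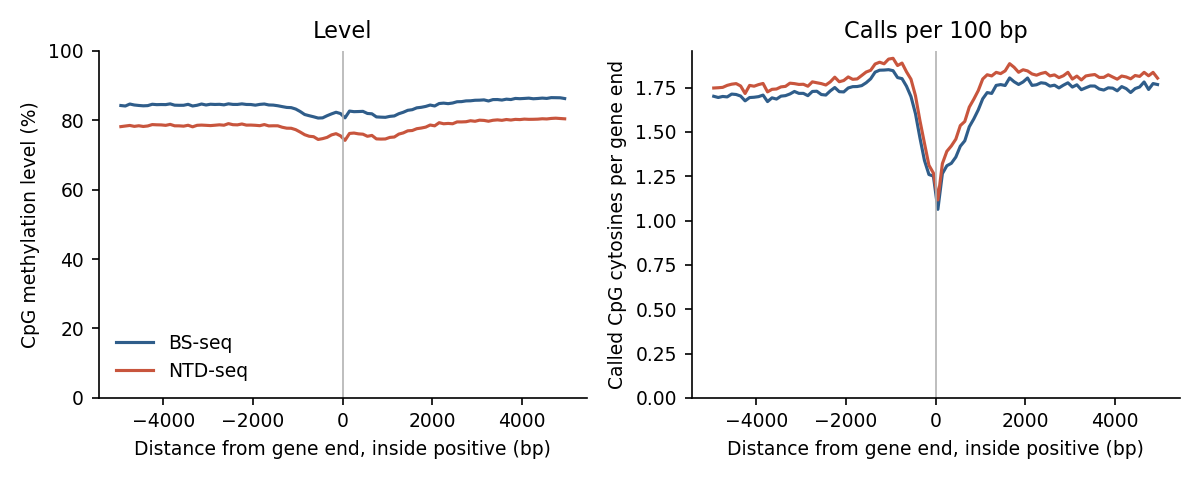
CpG methylation level in percent (left) and called CpG cytosines per gene end and 100 bp (right) against the distance in bp from the ends of 14,316 protein-coding genes, positive inside the gene, both ends pooled. Calls fall to 1.12 per end in NTD-seq and 1.06 in BS-seq at the first step inside, and the NTD-seq level stays below the BS-seq level along the whole window.

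Gene groups fixed in advance kept the same order of levels in both libraries at the extremes. Genes of the DNA methylation machinery had the highest medians, 83.0% in NTD-seq and 89.8% in BS-seq. Housekeeping genes followed with 82.4% and 87.8%. Olfactory receptor genes had the lowest, 53.3% and 57.7%. The median difference of the 13 groups ran from −4.88 points (olfactory receptors) to −6.62 points (HOX clusters). A percentile below gives the place of a group's median among 10000 random groups of the same size and level, and describes these libraries only.

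All 25 housekeeping genes were lower in NTD-seq, none by as much as 10 points with separate intervals (median −5.87 points, percentile 36.1, or 62.8 when averaged over sites). LTAP1, listed under its older symbol C1orf43, was the highest in NTD-seq at 87.7%, against 93.6% in BS-seq, and the small GTPase gene RAB7A was the median at 82.4% and 88.9%. EEF1A1, which encodes a translation elongation factor, was the lowest at 41.7% and 51.5%, with intervals that overlapped (−9.84 points, or −5.69 as a mean over sites). The 18 genes of the DNA methylation machinery were also all lower in NTD-seq with separate intervals (median −6.19 points, percentile 6.49). The maintenance methyltransferase gene DNMT1 had 87.8% and 92.5%, the oxidase gene TET3 had 82.3% and 88.6%, and the stress gene GADD45A had 62.2% and 71.9%. The difference of GADD45A was −9.71 points weighted by reads and −3.91 points as a mean over sites. APOBEC3A, a cytidine deaminase gene, was the only member of this group at least 10 points lower with separate intervals, at 71.8% and 83.8%; it was named after its value was seen.

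Of 29 imprinted genes 28 were measured, all lower in NTD-seq (median −5.83 points, percentile 36.9, or 66.9 when averaged over sites), 18 of them with separate intervals. NNAT had 88.8% in NTD-seq and 97.0% in BS-seq, SGCE had 75.9% and 79.9%, and MCTS2 was the lowest at 44.2% and 51.1% with intervals that overlapped (−6.94 points, or −3.93 as a mean over sites). MAGEL2 alone was lower by at least 10 points with separate intervals (67.8% and 78.5%, named after its value was seen). All 24 germline genes were lower with separate intervals (median −5.71 points, percentile 60.6), from SYCP3, a gene of the synaptonemal complex, at 84.7% and 93.6%, through CTCFL at 79.0% and 83.5%, to PIWIL1, an Argonaute family gene of the germline, at 47.9% and 51.8%.

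Of 30 developmental regulators 28 had enough calls, and 27 were lower in NTD-seq (median −5.62 points, percentile 76.7). HAND2 was the highest at 89.5% and 95.9%, GATA4 had 80.3% and 87.4%, and HAND1 was the lowest at 59.1% and 63.2% with intervals that overlapped (−4.03 points, or −7.07 as a mean over sites). FOXA1 alone had the higher value in NTD-seq, 75.1% against 71.8%, within counting error (3.38 points, interval −0.661 to 7.42; named after its value was seen). The HOX clusters, which set position along the body axis, spread more widely. Of 38 measured HOX genes 37 were lower in NTD-seq and 7 were lower by at least 10 points with separate intervals. HOXD10 (chromosome 2, 176115930 to 176120913) had 90.2% in NTD-seq and 96.2% in BS-seq, HOXB5 had 70.1% and 79.4% (−9.29 points, or −5.76 as a mean over sites), and HOXA9 (chromosome 7, 27161514 to 27166104) had 24.4% and 32.2%. The group's median difference of −6.62 points lay at percentile 0.06, and at 1.97 when levels were averaged over sites. Protocadherin cluster genes, whose spans overlap, had a median of −6.54 points at percentile 0.14, and 9.02 when averaged over sites. Of these 54 genes 53 were lower in NTD-seq, with PCDHGC5 at 75.7% and 83.1%, PCDHA2 at 61.9% and 67.6%, and PCDHB10 at 48.1% and 49.3%. Within counting error, the difference of PCDHB10 went from −1.24 points to 0.788 as a mean over sites. Members of a cluster share sites and neighbours, so these percentiles are no test.

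Of 390 olfactory receptor genes 284 had enough calls. In NTD-seq 232 were lower and 52 higher, 66 of them with separate intervals. Of these 66, 23 were lower by at least 10 points and 0 were higher by as much. OR13J1 was the highest in NTD-seq at 85.0% (89.0% in BS-seq), OR10H5 was the median at 53.2% (51.9%), and OR51T1 was the lowest at 21.9% (34.3%), each with intervals that overlapped. As a mean over sites the difference went from 1.29 to −0.874 points in OR10H5 and from −3.94 to −1.32 in OR13J1. The median difference of −4.88 points lay above all of the random groups, at percentile 100. The group's median BS-seq level lay at percentile 4.47 among genes, and matching in 10 classes leaves levels unequal inside a class. The difference between the libraries shrank at lower levels, so unequal levels may account for part of this place. The percentile is therefore no test.

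**Figure D4:**
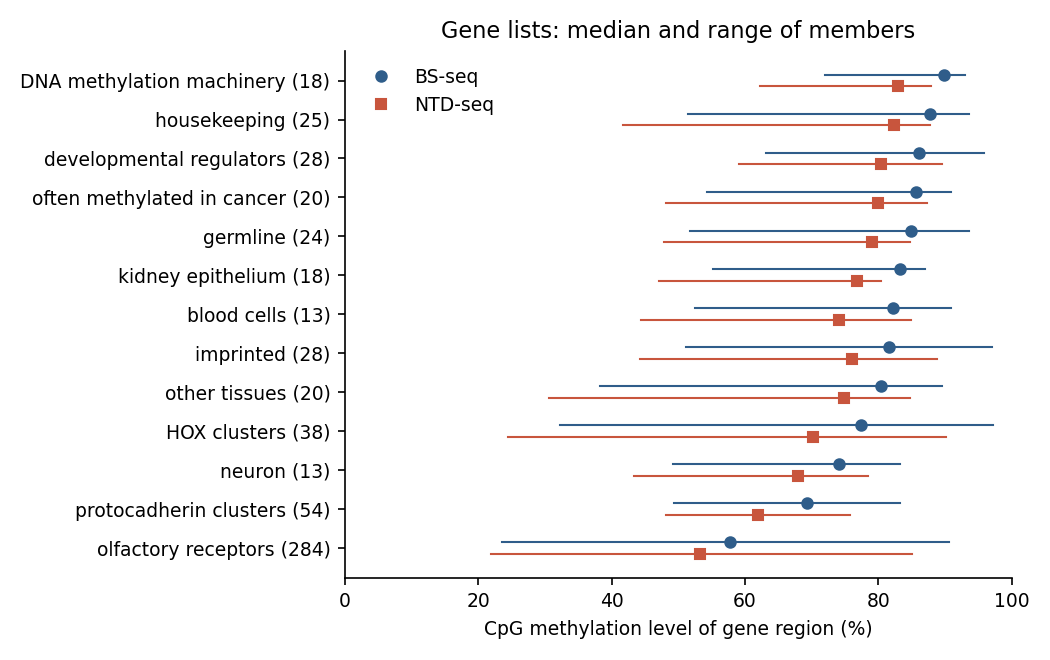
Median (marker) and range over members (line) of the CpG methylation level of gene regions in percent, for the 13 gene groups, with the number of measured genes in brackets. The NTD-seq median lies below the BS-seq median in each group, from 53.3% against 57.7% for olfactory receptors to 83.0% against 89.8% for the DNA methylation machinery.

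Genes often methylated in cancer were lower in NTD-seq in 20 of 20 cases (median −5.28 points, percentile 95.9). TWIST1 had 87.2% and 90.9%, NDRG4 had 79.6% and 84.9%, and CDH13, a long cadherin gene, had 48.2% and 54.2%. TFPI2 alone was lower by at least 10 points with separate intervals (66.2% and 79.4%, named after its value was seen). Kidney epithelium genes were lower in 18 of 18 cases with separate intervals (median −5.96 points, percentile 27.2), with the phosphate transporter gene SLC34A1 at 76.6% and 83.6% and the calcium-binding protein gene CALB1 at 47.1% and 55.2%.

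Marker genes of neurons, blood cells and other tissues had lower medians in both libraries than housekeeping genes. The 13 neuron genes had medians of 67.9% in NTD-seq and 74.1% in BS-seq (difference −5.45 points, percentile 69.1), from the tubulin gene TUBB3 at 78.4% and 83.3%, through MAP2 at 67.9% and 74.1%, to DCX at 43.4% and 49.3%. The 13 blood cell genes had 74.0% and 82.3% (difference −6.29 points, percentile 10.3, or 5.5 when averaged over sites). CD14 had 84.8% and 89.1%, CD3E had 74.0% and 79.96%, and the beta-globin gene HBB had 44.4% and 57.9% on 6 cytosines. CD3D alone was lower by at least 10 points with separate intervals (74.0% and 84.8%, named after its value was seen). The 20 genes of other tissues had 74.8% and 80.3% (difference −4.98 points, percentile 98.9), with the skeletal actin gene ACTA1 at 84.7% and 89.5%, the muscle creatine kinase gene CKM at 74.7% and 82.1%, and the trypsinogen gene PRSS1 at 30.6% and 38.2%.

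Outside CpG, NTD-seq called 66,516 CHG and BS-seq 70,764, with 46,600 in both. These numbers come from unlike limits, since the background rate behind the CHG calls was 0.969% in NTD-seq and 0.306% in BS-seq, and a call had at least 3 and 2 methylated reads. In the CHH context (H stands for A, C or T) NTD-seq called 795,132 cytosines and BS-seq 208,361, a ratio of 3.82, with 145,960 in both. At the shared CHG calls the level was 67.1% (interval 66.9 to 67.2) in NTD-seq and 72.6% (72.4 to 72.7) in BS-seq. At the shared CHH calls it was 61.2% (61.1 to 61.2) and 66.8% (66.7 to 66.9). Both differences, −5.50 and −5.63 points, were close to that at CpG sites. The 649,172 CHH calls of NTD-seq alone had a median level of 16.7%, and 85.5% of them rested on at most 2 methylated reads. The 62,401 CHH calls of BS-seq alone had a median level of 40%. With the BS-seq background rate and p limit applied to both tables, the ratio fell to 1.17, an alternative chosen after the data were seen. All 208,361 BS-seq calls had already passed that limit, so only NTD-seq could lose calls, and 242,773 of its calls stayed.

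**Figure D5:**
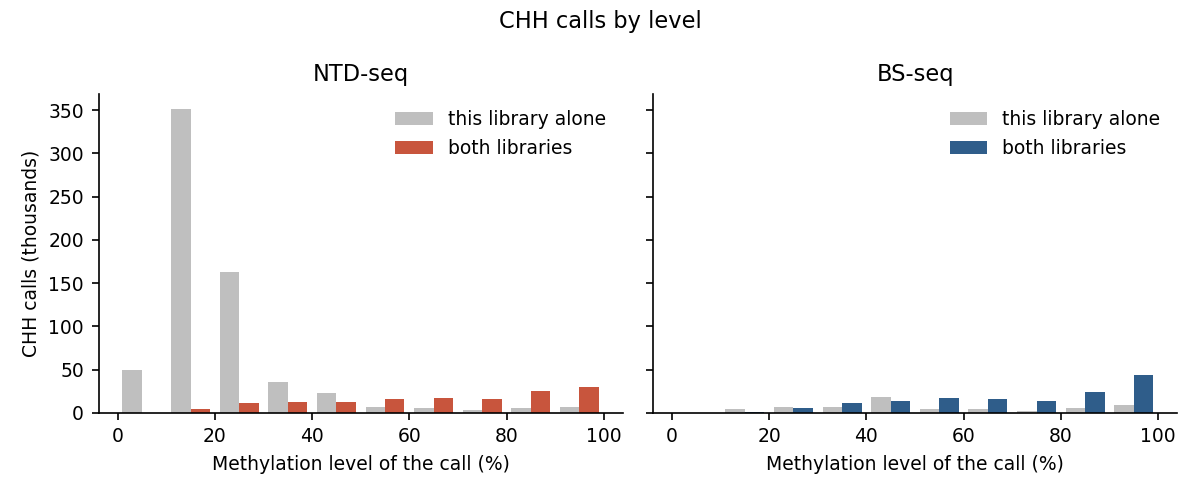
Number of CHH calls in units of 1000 (vertical axis) by methylation level of the call in percent (horizontal axis, classes of 10 points) in NTD-seq (left) and BS-seq (right), for calls made in that library alone (grey) and in both (coloured). The 649,172 calls of NTD-seq alone gather at low levels, with a median of 16.7%.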

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

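The windows around gene starts, CpG islands, GC content and flanking bases read from the genome were not run. Alternatives for shared calls, gene windows and the background rate of CHH calls were chosen after the data were seen. No paired analysis was possible because there was 1 library per method.

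The CpG level was lower in NTD-seq in each setting tried. Against −6.48 points over all called CpG cytosines, the difference was −5.84 at cytosines called in both, −5.67 with at least 10 reads in both, −6.63 with at least 20 reads in both, −5.20 as an unweighted mean over cytosines with at least 10 reads, which changes weights and depth together, −6.44 without the deepest sites and −6.47 after subtracting the background rate. Site correlation followed depth, from 0.687 with at least 5 reads to 0.910 with at least 20. It was 0.801 without the deepest sites and 0.825 with both strands summed. Against 20 sites called lower by Fisher's test, there were 38 at a limit of 10 points and 11 at 30 points, 13 at a minimum of 5 reads, 50 at 20 reads, 13 after thinning to equal depth and 0 without the deepest sites. None was higher in NTD-seq in any of these settings.

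Bin correlation was 0.977 at 10 kb, 0.998 at 1 Mb and 0.996 without the deepest sites, and the median difference was −5.55 points at 10 kb and −5.68 at 1 Mb. The median difference of gene regions was −5.58 points as a mean over sites and −5.76 without flanks, and that of gene bodies −5.59 as a mean over sites. Averaging over sites lowered the number of gene regions at least 10 points lower from 415 to 233, and of gene bodies from 213 to 139. A limit of 20 points left 11 regions and 0 bodies. Without flanks 1 region was higher in NTD-seq by at least 10 points with separate intervals. UCN3 reversed when averaged over sites, to −5.63 points for the region and −6.27 for the body; the cause was not tested further than this change of weights. Of 112 values for single named genes, 103 stayed within counting error, 7 moved beyond it and 2 reversed. Each of the 26 values for the medians of gene groups stayed within the counting error of a typical single member, which is a wide limit.

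CHG levels over all calls differed by −2.34 points, by −0.254 with at least 10 reads and by −5.50 at shared calls. CHH levels differed by −35.9 points, by −33.6 with at least 10 reads and by −5.63 at shared calls, which leave out the calls that NTD-seq made alone. The ratio of CHH calls went from 3.82 to 1.17 with the BS-seq rate and limit in both, a filter that could remove NTD-seq calls alone. Depth seemed to limit single sites most, given the low share of simulated changes that Fisher's test recovered in a smaller set of sites. Gene regions were tested on simulated changes of 15 and 30 points alone, and those with few reads have wide intervals, such as −41.0 to −11.8 points for OR2T33. The cause of the other shifts was not tested.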

Other observations

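Median levels of the HOX clusters are given here without a test, since their genes are neighbours and the ranges overlapped. The HOXA genes had the lowest median gene region level, 49.4% in NTD-seq and 57.8% in BS-seq over 11 genes, and ran from 24.4% (HOXA9) to 84.95% in NTD-seq. The HOXD genes had the highest, 86.0% and 91.0% over 9 genes, and ran from 56.5% to 90.2% in NTD-seq. HOXB genes had medians of 70.8% and 79.4%, and HOXC genes 69.8% and 77.9%. The member with the largest fall in NTD-seq was HOXC11 (45.4% and 62.3%, −16.9 points, interval −20.7 to −12.9), singled out after its value was seen.

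Gene groups also lay in different parts of the regional map. Of 19,798 protein-coding genes in a measured 100 kb bin, 8.05% lay in bins under 65% in BS-seq. Of 351 olfactory receptor genes 232 (66.1%) did, of 54 protocadherin cluster genes 21, of 39 HOX genes 10 and of 13 neuron genes 4. None of 25 housekeeping genes and none of 18 genes of the DNA methylation machinery did. Neighbouring genes share bins, so these shares describe the map and are not tests. Depth differed between chromosomes alike in both libraries, from a median per bin of 13.8 reads in NTD-seq and 11.6 in BS-seq on chromosome 1 to 9.19 and 7.56 on chromosome 18.

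For the patterns weighed here, the tests of read depth and of a fixed loss of unmethylated reads behind the lower CpG levels, and of both explanations for the CHH calls, were chosen after the result was seen. No biological explanation was tested for any of them, since the labels give no difference between the groups other than the method. Other differences between the 2 libraries are not known.

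For the lower CpG levels of NTD-seq, depth and the calling threshold would bring the difference under 2 points at cytosines with at least 20 reads in both, where it was −6.63 points. As an unweighted mean over the same 366,940 cytosines the difference was −4.76 points. If BS-seq had lost the same share of unmethylated reads at every level, the 49.3% that gives the −5.66 points of the class of 95 to 100% would give −14.1 points in the class of 50 to 80%. The difference there was −5.03 points, 0.356 times that (0.308 to 0.383 over the autosomes), which argues against a fixed loss as the whole cause. Of a loss at any share, 2 predictions were made before the result was seen. The difference would be larger at intermediate levels than at high ones, which it was not. A difference of 2 points or more in the top class would speak against a loss, and the difference was −5.66 points. Both results went against a loss. NTD-seq was at 87.7% there, which leaves room for more than 2 points, a condition that was not part of the prediction. Under that added condition a loss that grows with the level stays open. Incomplete protection of methylated cytosines in NTD-seq also stays open as a hypothesis. The NTD-seq level was 0.939 times the BS-seq level in the top class and 0.926 times in the class of 50 to 80%. A loss of a fixed share of methylated reads may give that. In the class of 5 to 20% it was 0.859 times, which a fixed share alone does not account for. Only cytosines called in both libraries enter, a selection that weighs most at low levels. The ratio of the lowest class may therefore reflect the calling in part.

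The excess of CHH calls in NTD-seq may come from the background rate and p limit behind the calls. With those of BS-seq in both tables, the ratio of calls was 1.17 in place of 3.82. The rate and the limit were changed together, so the part of each is not known. This filter could only lower the ratio, since it removed NTD-seq calls and could add none to BS-seq. That the ratio fell is therefore no support in itself, and only the size of the fall was left open by the filter. Strands left unconverted over a stretch would put other such calls nearby on the same strand. Of the CHH calls that BS-seq lacks, 2.71% had another within 50 bp. That share was 3.42% among CHH calls of BS-seq alone and 1.14% among shared ones, in sets of unlike size. A CHH call rested on at least 2 methylated reads, so a single unconverted strand would seldom make a call. The low share therefore cannot exclude such strands. Single unconverted cytosines remain open too.

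The non-CpG cytosines called in both libraries may in part be CpG sites in this cell line that the reference does not have. Of those with at least 20 reads in both, 37.1% had a BS-seq level 0.8 to 1.2 times that of the CpG cytosines within 1 kb. A ratio of 0.4 to 0.6 was seen at 13.4% and a ratio below 0.4 at 19.8%. No other set of cytosines was measured beside these, so what share would arise without variants is not known. Of 46,600 shared CHG calls only 4 had the matching cytosine of the other strand called. CHG methylation of 1 strand alone would give the same, so this count cannot tell it from variants. Reads mapped to the wrong copy would raise depth, but the median depth was at most 1.1 times that of CpG calls, which argues against collapsed copies as the main source. Sequence variants themselves were not examined, and the remaining calls are unexplained.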
